A study of Mus musculus with 24 samples.

How the data were processed

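PolyA RNA was sequenced on libraries made with the Illumina TruSeq v2 kit, from 24 samples in 8 groups of 3 biological replicates. The groups are whole liver or isolated hepatocytes from WT, IkkB KO, Shp2 KO and Double KO mice, and the labels assign each sample to 1 group. RNA was extracted with RNeasy kits that differ between whole liver and hepatocytes. Reads were processed with FastQC and Cuffdiff against the mouse build mm9, per the submitters' processing notes. The aligner, the annotation and the versions of these programs are not given in the sources used here. Strand was not stated, so values of overlapping or antisense genes are uncertain. Values of near-identical genes (the Mup, Cyp4a12, Saa1 and Saa2 families, and pseudogenes) are uncertain as well, since reads can be assigned to either copy.

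The authors deposited 1 table for liver and 1 for hepatocytes, each a Cuffdiff comparison of pairs of genotypes. The expression values deposited by the authors are 1 value per gene and genotype, in a unit the header does not name (other), and by the convention of Cuffdiff they are FPKM. The log2 fold changes deposited by the authors are log2 ratios of these values. The deposited test statistic is a score, per the file headers, and was not used. The p-value and q-value columns are the authors' Cuffdiff tests, where the q-value is a Benjamini-Hochberg adjusted p-value. The liver q-values were recomputed from the p-values of all 6 pairs together, with a largest difference of 5.27e-07. The hepatocyte q-values could not be recomputed from the 5 pairs in that table, with a largest difference of 0.284. Smallest values were 5e-05 for p in both tables and 0.000955 (liver) and 0.00048 (hepatocytes) for q. The tables hold no value per replicate (0 columns per sample), no read counts and no library sizes. Depth and the precision it gives are therefore unknown, and no SD, interval or test across samples was computed.

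Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Genes were called when the authors' q-value was under 0.05, among genes that Cuffdiff tested and that had a value of at least 0.1 in 1 of the 2 genotypes. Each table had 5 comparisons: every knockout against WT, and Double KO against each single knockout. Differences were computed as log2(value + 1). Genes too abundant for Cuffdiff to test in any pair (38 in liver, 27 in hepatocytes) were left out of correlations and of the comparison with the sum of single effects. Among these, Alb was listed at 0 in all genotypes.

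Lists of genes, 28 in all and 9 of them cell type markers, were fixed in advance. For each, members past the threshold were counted, also with the p-values adjusted over the list alone. The median difference of the tested members was ranked among 10000 random lists matched on expression, where a rank within 2.5% on either side describes these libraries only. Of 168 combinations of list and comparison against WT, 100 lay within that range. Lists were also simulated with normal noise independent between genes, where every member of a changed list was shifted by the full fold. On these data 40 of 40 changed lists were recovered at folds of 1.5 and 2.0 in both tables, and 1 of 40 (liver) and 2 of 40 (hepatocytes) unchanged lists were called. Genes that vary together were not simulated, so these numbers do not give the rate of false placements among the real lists. List membership overlaps by at most 2 genes per list.

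The genes named against WT were chosen by a rule fixed in advance: Ikbkb and Ptpn11, up to 4 members per list that passed (smallest adjusted p-value first), and the 5 largest rises and 5 largest falls with a value of at least 1. Members of the clock list could be named whether or not they passed, and not every gene that met the rule is named. Between knockouts, only genes named by that rule and the clock list were used. Effects were set side by side with Pearson and Spearman correlations across genes at a value of at least 1 in either genotype. Correlations that shared a control were set beside simulated groups without an effect. Their noise was normal, and its size was the median, per group of genes of like expression, of the absolute difference over the normal score of the authors' p-value, for p-values between 0.001 and 0.9. No replicate values were there to check it. The Double KO was compared with the sum of the single effects without a test. Alternatives tried were the pseudocount 0.1, other filters on low values, a q-value under 0.01, a log2 difference of at least 1, centring on the median and random lists not matched on expression. Benjamini-Hochberg adjustment within a comparison and pairs without a shared genotype were added after the data were seen.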

Results

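RNA was sequenced from 24 samples of 2-month-old male mice, 12 of whole liver and 12 of isolated hepatocytes, the main epithelial cells of the liver. Each set of 12 held 4 genotypes with 3 biological replicates per genotype: wild-type C57/BL6 controls, and knockouts of IkkB, of Shp2 and of both, made with Cre recombinase driven by the albumin promoter. Shp2, encoded by Ptpn11, is a tyrosine phosphatase that relays growth factor signals to Ras and Erk, and IkkB, encoded by Ikbkb, is a kinase that activates NF-κB. The series title frames the question as the effect of disrupting both pathways together on the circadian clock and on liver cancer. The deposited tables give 1 expression value per gene and genotype, over 24319 genes, and no value per replicate. No SD can therefore be given, and the depth of each library is unknown. The values are those of the authors, called FPKM (fragments scaled for transcript length and library size) after the usual output of the program. "Rose" and "fell" below mark genes past the threshold on the q-value in the authors' deposited table, which is the only measure of replicate error here. The liver and hepatocyte tables were made separately, so levels are compared within a table.

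Both deletions were visible in the targeted transcripts. In whole liver, Ikbkb was 15.7 in WT, 14.2 in Shp2 KO, 9.48 in IkkB KO and 6.31 in Double KO. Ptpn11 in the same table was 12.5 in WT, 10.1 in IkkB KO, 4.09 in Shp2 KO and 6.09 in Double KO. In isolated hepatocytes, Ikbkb was 17.3, 15.1, 7.16 and 5.29 in WT, Shp2 KO, IkkB KO and Double KO, in that order. Hepatocyte Ptpn11 was 16.3 in WT, 14.5 in IkkB KO, 4.46 in Shp2 KO and 5.77 in Double KO. Each gene fell in the genotypes labelled as lacking it, with q = 0.000955 in liver and 0.00048 in hepatocytes in the authors' deposited table. In the authors' deposited table the gene that was not deleted had q from 0.366 to 0.774 in the single knockouts.

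**Figure D1:**
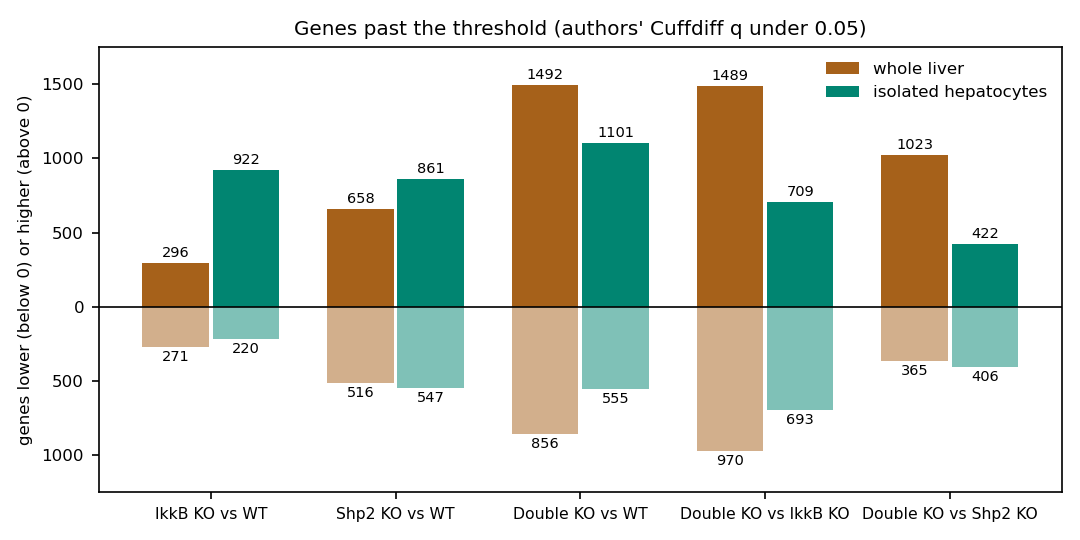
Number of genes higher (above the axis) and lower (below the axis, paler) in the first-named genotype of each comparison, for whole liver (brown) and isolated hepatocytes (green), at a q-value under 0.05 in the authors' table. The numbers above and below the bars are the counts, such as 1492 higher and 856 lower genes in Double KO liver against WT.

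In IkkB KO liver, acute phase and metallothionein transcripts and male-biased transcripts were lower and female-biased ones higher. The metallothioneins Mt2 and Mt1, which bind zinc and copper, fell from 1032 to 44.7 and from 1675 to 133. Saa1, an acute phase protein, fell from 534 to 122, and the NF-κB target Cxcl1, a neutrophil chemokine, fell from 19.4 to 4.16. In the acute phase list, 3 rose and 7 fell of 26 tested members (4 and 7 adjusted over the list alone); the list median was -0.30, and 0 of 10000 random lists lay as low. The endoplasmic reticulum stress genes Creld2, Derl3 and Sdf2l1 fell from 97.3 to 27.5, from 9.05 to 2.502 and from 48.5 to 18.1. Of the stress response list, 8 of 18 tested members fell (9 adjusted over the list alone). Male-biased Cyp4a12a fell from 141 to 46.1 and Elovl3, a fatty acid elongase, from 101 to 36.6, while Cyp2a4 and Cyp17a1, steroid-metabolising enzymes of the female-biased list, rose from 0.416 to 11.4 and from 4.11 to 16.8. In the male-biased list, 8 of 14 tested members fell (11 adjusted over the list alone), and in the female-biased list, 11 of 13 tested members rose (11 adjusted over the list alone).

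Several clock repressors were higher in IkkB KO liver. Of the circadian clock list, 5 rose and 2 fell of 18 tested members (5 and 3 adjusted over the list alone); the list median was 0.21, and 1 of 10000 random lists lay as high. Per1, Per2 and Per3, repressors of the clock, rose from 13.2 to 20.5, from 9.795 to 14.4 and from 7.25 to 10.8, as did Ciart, from 21.3 to 31.7. Clock and Bhlhe41 fell from 2.004 to 1.33 and from 2.16 to 1.34. Output genes Usp2 and Tsc22d3 rose from 18.1 to 31.8 and from 65.8 to 115, and of the clock output list, 5 of 18 tested members rose (9 adjusted over the list alone). The labels give no time of collection for any sample. Immediate early genes went both ways: Dusp1, Nr4a1 and Fos fell from 38.4 to 14.2, from 5.09 to 2.43 and from 1.201 to 0.4805, and the heat shock gene Hspa1b rose from 2.804 to 6.52. In that list, 2 rose and 5 fell of 16 tested members (3 and 5 adjusted over the list alone). NF-κB targets were also mixed, since 3 rose and 1 fell of 22 tested members (3 and 2 adjusted over the list alone); Ccl5 and Nfkbia rose from 4.12 to 11.7 and from 23.9 to 38.9. Marker transcripts of macrophages rose in part, with Marco from 2.78 to 11.8 and Cd74 from 90.6 to 193 (4 of 17 tested members rose, 4 adjusted over the list alone). Bile duct markers such as Spp1, from 52.5 to 31.1, and Sox9, from 1.18 to 0.4596, fell (5 of 12 tested members fell, 6 adjusted over the list alone). Among genes outside the lists, the interferon-induced GTPase Igtp rose from 20.5 to 92.2 and the signalling regulator Rgs16 from 38.9 to 161. In all, 567 of 12484 tested genes passed the threshold, 296 higher and 271 lower. None of the 15 gluconeogenesis and glycogen genes passed in the Cuffdiff test, where 6 were higher and 0 lower at an unadjusted p under 0.05 in the authors' deposited table.

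Hepatocytes isolated from IkkB KO mice had lower acute phase transcripts, as in whole liver, and higher transcripts of non-hepatocyte cells; differences between the tables were not tested. Saa2 fell from 1299 to 58.6, Saa1 from 1998 to 127, Mt2 from 464 to 16.8 and Mt1 from 573 to 55.3, and of the acute phase list, 1 rose and 12 fell of 26 tested members (1 and 12 adjusted over the list alone); the list median was -0.63, and 0 of 10000 random lists lay as low. Cxcl1 fell from 32.2 to 3.902. The p53 target Cdkn1a, an inhibitor of the cell cycle, fell from 11.5 to 2.73, and in its list, 1 rose and 2 fell of 18 tested members (1 and 2 adjusted over the list alone). Markers of non-hepatocyte cells were higher than in the WT preparations in the macrophage, stellate cell and endothelial lists. In the macrophage list, 14 of 14 tested members rose (14 adjusted over the list alone), with Marco from 1.08 to 21.9 and C1qa from 17.01 to 53.8. In the stellate cell and fibroblast list, 15 of 15 tested members rose (15 adjusted over the list alone), with Dcn from 20.6 to 84.8, and in the endothelial list, 14 of 15 tested members rose (14 adjusted over the list alone), with Clec4g from 22.2 to 45.3. The macrophage and stellate cell lists had 19 members each with deposited values, so not all were tested. A member near 0 in WT is tested only if its knockout value is high enough, which favours rises. Antigen presentation genes H2-Aa and H2-Eb1, abundant in immune cells, were among the 5 largest rises, from 13.2 to 87.9 and from 6.91 to 52.5.

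These marker rises stand beside the other genes that rose. Vcam1 rose from 0.885 to 5.29 and Ccl2 from 0.285 to 1.28 in the NF-κB list (3 rose and 2 fell of 20 tested members, 3 and 2 adjusted over the list alone). Cell cycle transcripts rose from low levels, Mki67 from 0.133 to 0.585 and Top2a from 0.247 to 0.736 (10 of 25 tested members rose, 11 adjusted over the list alone). Ras-Erk feedback targets Ccnd1 and Dusp6 rose from 4.93 to 13.4 and from 8.64 to 14.4 and Phlda1 fell from 107 to 58.3 (4 rose and 1 fell of 13 tested members, 5 and 1 adjusted over the list alone). Lipid genes Elovl6 and Acaca, of fatty acid synthesis, rose from 22.4 to 43.3 and from 6.12 to 10.4 (5 of 21 tested members rose, 5 adjusted over the list alone), and Rgs16 again rose, from 13.8 to 141. Of the clock list, 1 rose and 3 fell of 19 tested members (1 and 3 adjusted over the list alone): Arntl, Npas2 and Nfil3 fell from 4.81 to 1.74, from 0.483 to 0.146 and from 21.96 to 8.09, and Bhlhe41 rose from 0.639 to 1.18. Male-biased genes fell in part, Cyp4a12b from 35.4 to 9.83 and Elovl3 from 139 to 57.7 (6 of 15 tested members fell, 6 adjusted over the list alone). Altogether 1142 of 12135 tested genes passed, 922 higher and 220 lower. In the cholesterol synthesis list, 1 of 23 tested members fell (0 adjusted over the list alone), which was Mvk, from 24.4 to 16.5.

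In Shp2 KO liver, feedback genes of Ras-Erk signalling were lower, and genes of cholesterol synthesis and detoxification higher. Ccnd1, which encodes cyclin D1, fell from 20.3 to 5.14, and the pathway inhibitors Spry4, Dusp6 and Spred1 fell from 2.33 to 0.346, from 12.1 to 4.61 and from 1.91 to 0.583. Of the Ras-Erk feedback list, 8 of 14 tested members fell (8 adjusted over the list alone); the list median was -0.57, and 0 of 10000 random lists lay as low. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 29.97 to 135 and Cyp8b1 rose from 136 to 514, while Nr0b2, a receptor that represses both, fell from 39.6 to 7.32. In the bile acid synthesis list, 3 rose and 2 fell of 16 tested members (4 and 2 adjusted over the list alone); the list median was 0.08, and 1515 of 10000 random lists lay as high. Export pumps Abcc4 and Abcc3 rose from 0.302 to 1.6 and from 37.9 to 69.6, and the uptake carrier Slco1a1 fell from 107 to 29.9 (5 rose and 2 fell of 17 tested members, 5 and 2 adjusted over the list alone). Fdps, an enzyme of cholesterol synthesis, rose from 219 to 471. In the cholesterol synthesis list, 13 of 23 tested members rose (15 adjusted over the list alone); the list median was 0.72, and 0 of 10000 random lists lay as high. Glutathione transferase Gstm3 rose from 62.01 to 236 among Nrf2 targets (12 rose and 2 fell of 20 tested members, 15 and 3 adjusted over the list alone).

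Among fatty acid oxidation genes, some rose, such as Cyp4a14 from 5.39 to 244 (7 of 22 tested members rose, 7 adjusted over the list alone). Lipid uptake gene Cd36 rose from 4.85 to 25.8 and Pparg from 4.12 to 17.3 (5 rose and 2 fell of 21 tested members, 5 and 3 adjusted over the list alone). Hsd3b5, a male-biased steroid enzyme, fell from 278 to 4.29, whereas male-biased Cyp4a12a rose from 141 to 434; in that list, 3 rose and 10 fell of 14 tested members (3 and 11 adjusted over the list alone). Mt2 fell from 1032 to 99.6, Cxcl1 fell from 19.4 to 5.16, and the acute phase gene Orm2 rose from 14.8 to 126; in the acute phase list, 4 rose and 6 fell of 26 tested members (5 and 7 adjusted over the list alone). Proliferation transcripts rose from low levels, Cdk1 from 0.698 to 1.78 and Mki67 from 0.184 to 0.533 (13 of 27 tested members rose, 16 adjusted over the list alone). Ly6d rose from 1.94 to 65.3 in the fetal and tumour list, and Tff3 fell from 36.1 to 8.03 (4 rose and 2 fell of 17 tested members, 4 and 2 adjusted over the list alone). Endothelial markers Lyve1 and Kdr fell from 3.79 to 1.39 and from 5.61 to 3.35 (5 of 16 tested members fell, 7 adjusted over the list alone), and of the macrophage list, 7 of 19 tested members rose (11 adjusted over the list alone). In the lymphocyte list, 3 of 13 tested members fell (3 adjusted over the list alone), with Cd4 from 0.824 to 0.3097. Of the clock list, 2 of 18 tested members fell (2 adjusted over the list alone), Bhlhe40 from 76.6 to 40.9 and Bhlhe41 from 2.16 to 1.22. In the pancreatic acinar list, 1 of 2 tested members fell (1 adjusted over the list alone), which was Cela1, from 34.6 to 6.24. Outside the lists, Csad, which makes a precursor of the taurine used for bile acid conjugation, rose from 74.4 to 749, and Rgs16 fell from 38.9 to 2.95. Of 12588 tested genes 1174 passed, 658 higher and 516 lower.

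In Shp2 KO hepatocytes most of the female-biased list was higher, cholesterol synthesis genes were higher and Ras-Erk feedback genes lower. Cyp2b9, a cytochrome P450 of female mouse liver, rose from 0.165 to 53.9, the sulfotransferase gene Sult2a1 from 0.0888 to 47.6 and Cyp2a4 from 1.24 to 39.3. The female-biased list has 21 members, of which 16 were tested and 14 of these rose (14 adjusted over the list alone). The median of the tested members was 2.13, and 0 of 10000 random lists lay as high. A member near 0 in WT enters the test only if its knockout value is high enough, which favours rises. The 3 libraries are pooled in these values, so a rise in 1 of them was not separated from a rise in all. In whole liver of the same genotype 6 rose and 2 fell of 12 tested members of the list (8 and 2 adjusted over the list alone); the list median was 0.52, and 0 of 10000 random lists lay as high. Cyp2b9 was 0.0402 in WT and 0.0429 in Shp2 KO liver. Male-biased Hsd3b5 fell from 149.6 to 1.397 and the urinary protein gene Mup1 from 137 to 4.52 (1 rose and 13 fell of 15 tested members, 2 and 13 adjusted over the list alone). The Mup genes are near-identical copies, so reads can be split among them. Spry4 fell from 2.78 to 0.375 and Dusp6 from 8.64 to 3.401 (2 rose and 7 fell of 12 tested members, 2 and 7 adjusted over the list alone). Cyp7a1 rose from 24.6 to 97.0 and Nr0b2 fell from 55.9 to 21.97; in the bile acid synthesis list, 2 rose and 4 fell of 16 tested members (3 and 4 adjusted over the list alone); the list median was 0.02, and 4084 of 10000 random lists lay as high. Abcb1a and Slc51b, both exporters, rose from 0.407 to 4.801 and from 2.7 to 18.98 (6 rose and 1 fell of 16 tested members, 6 and 1 adjusted over the list alone).

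The cholesterol enzyme gene Cyp51 rose from 50.4 to 116 (14 of 23 tested members rose, 15 adjusted over the list alone). Cyp4a14 rose from 9.77 to 344, Cd36 from 2.31 to 55.9 and Pparg from 0.914 to 10.3, and in the fatty acid oxidation list, 8 of 22 tested members rose (8 adjusted over the list alone). Acute phase transcripts were higher, and a difference from IkkB KO hepatocytes was not tested. Orm2 rose from 41.6 to 627 and Lcn2 from 56.3 to 237 (9 rose and 2 fell of 26 tested members, 10 and 2 adjusted over the list alone). Hmox1, which degrades heme, rose from 6.52 to 25.8 among Nrf2 targets (10 rose and 2 fell of 20 tested members, 13 and 2 adjusted over the list alone). NF-κB targets Icam1 and Tnfaip3 rose from 3.25 to 9.45 and from 0.491 to 1.996 (7 rose and 2 fell of 21 tested members, 7 and 2 adjusted over the list alone). H19, a fetal non-coding RNA, rose from 0.149 to 24.5 and Ly6d from 0.632 to 31.9, while Glul, which makes glutamine, fell from 109.8 to 33.1; in the fetal and tumour list, 10 rose and 1 fell of 18 tested members (11 and 1 adjusted over the list alone). Asns, a target of the integrated stress response, rose from 1.15 to 7.76 and Xbp1 fell from 164 to 77.2 (2 rose and 3 fell of 18 tested members, 2 and 4 adjusted over the list alone). Of the clock list, 1 rose and 5 fell of 19 tested members (1 and 5 adjusted over the list alone): Arntl, Clock, Npas2, Cry1 and Nfil3 fell, Arntl from 4.81 to 1.51 and Nfil3 from 21.96 to 10.05, and Per1 rose from 6.84 to 10.6. Macrophage markers were again above the WT preparations, Marco from 1.08 to 14.5 (12 of 15 tested members rose, 13 adjusted over the list alone), as were some stellate cell markers (5 of 15 tested members rose, 6 adjusted over the list alone). None of the 15 endothelial markers passed in the Cuffdiff test, where 0 were higher and 0 lower at an unadjusted p under 0.05 in the authors' deposited table. In total 1408 of 12076 tested genes passed, 861 higher and 547 lower.

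Double KO whole liver, which kept 40.3% of the WT value of Ikbkb and 48.8% of that of Ptpn11, had the most calls against WT of the 3 knockouts. There 1492 genes were higher and 856 lower of 12940 tested. Transcripts of fetal liver and liver tumours, of dividing cells, of macrophages and of matrix-producing cells were higher. H19 rose from 0.4402 to 411, Igf2, a fetal growth factor, from 0.188 to 12.1, Ly6d from 1.94 to 129.8 and Scd2 from 1.24 to 10.5. Of the fetal and tumour list, 14 rose and 1 fell of 20 tested members (14 and 1 adjusted over the list alone); the list median was 0.76, and 0 of 10000 random lists lay as high. The mitotic genes Birc5 and Cdk1 rose from 1.04 to 6.18 and from 0.698 to 3.16 (17 of 27 tested members rose, 19 adjusted over the list alone). The collagen gene Col1a1 rose from 3.77 to 20.7 (14 of 19 tested members rose, 15 adjusted over the list alone). Macrophage markers Marco and Lyz2 rose from 2.78 to 23.4 and from 35.95 to 124 (19 of 19 tested members rose, 19 adjusted over the list alone). In the neutrophil list, 4 of 7 tested members rose (5 adjusted over the list alone), with S100a8 from 5.703 to 14.1. Spp1, a bile duct and macrophage transcript, rose from 52.5 to 137 (4 rose and 1 fell of 14 tested members, 5 and 1 adjusted over the list alone). Of the hepatocyte list itself, 1 rose and 2 fell of 16 tested members (1 and 2 adjusted over the list alone), and of the endothelial list, 1 of 16 tested members rose (1 adjusted over the list alone), which was Cdh5, from 4.78 to 7.48.

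Most acute phase genes that passed were higher, and a difference from IkkB KO liver was not tested. Orm2 rose from 14.8 to 649.6, Saa2 from 233 to 1280.1 and Lcn2 from 23.7 to 131, while Mt2 fell from 1032 to 220.1 (10 rose and 5 fell of 26 tested members, 11 and 6 adjusted over the list alone). Adhesion molecule Vcam1 rose from 2.62 to 9.13 and Cxcl1 fell from 19.4 to 8.15 among NF-κB targets (7 rose and 1 fell of 23 tested members, 11 and 1 adjusted over the list alone). Of the immediate early list, 9 rose and 2 fell of 16 tested members (9 and 3 adjusted over the list alone). The cell cycle inhibitor Cdkn1a rose from 1.805 to 7.98 (6 rose and 1 fell of 18 tested members, 7 and 1 adjusted over the list alone). Metabolic genes moved in both directions. Thrsp, a regulator of fat synthesis, fell from 868 to 198, and Cd36 rose from 4.85 to 37.3 (4 rose and 10 fell of 22 tested members, 4 and 10 adjusted over the list alone). The gluconeogenic gene G6pc fell from 326 to 103 (1 rose and 4 fell of 15 tested members, 1 and 5 adjusted over the list alone). Cyp4a14 rose from 5.39 to 384 (6 of 22 tested members rose, 6 adjusted over the list alone) and Cyp7a1 from 29.97 to 67.04, while Cyp7b1 fell from 228 to 27.8 (3 rose and 5 fell of 16 tested members, 3 and 5 adjusted over the list alone). Gstm3 rose from 62.01 to 349 (10 rose and 1 fell of 20 tested members, 15 and 1 adjusted over the list alone). Hsd3b5 fell from 278 to 0.666 and the carrier Slco1a1 from 107 to 5.27 (1 rose and 12 fell of 14 tested members, 1 and 12 adjusted over the list alone), and Cyp2a4 rose from 0.416 to 58.7 (12 rose and 1 fell of 15 tested members, 12 and 1 adjusted over the list alone). Of the Ras-Erk feedback list, 1 rose and 6 fell of 14 tested members (2 and 6 adjusted over the list alone), with Spry4 from 2.33 to 0.793.

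Most members of the clock list that passed were lower in Double KO liver. Per2, Per3, Hlf and Bhlhe40 were among those that fell, Per2 from 9.795 to 5.18 and Bhlhe40 from 76.6 to 37.6, and Per1 rose from 13.2 to 19.3 (1 rose and 6 fell of 18 tested members, 1 and 7 adjusted over the list alone); the list median was -0.29, and 14 of 10000 random lists lay as low. The core activators did not pass: Arntl was 0.449 in WT and 0.556 in Double KO, and Clock 2.004 and 2.11. Nr1d1, Dbp and Tef did not pass either, at 59.3 and 42.8, 115 and 82.3, and 59.6 and 49.5. Among outputs, Lpin1 fell from 76.9 to 34.98 and Usp2 rose from 18.1 to 29.9 (3 rose and 3 fell of 18 tested members, 3 and 3 adjusted over the list alone).

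**Figure D2:**
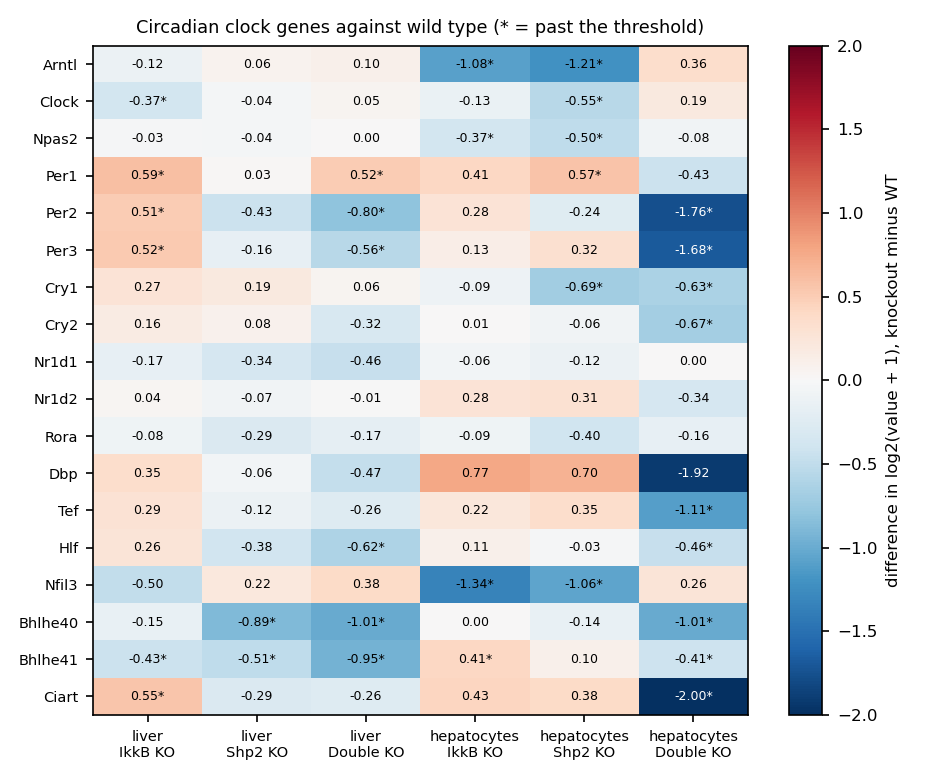
Difference in log2(value + 1) between each knockout and WT for 18 of the 19 genes of the circadian clock list (vertical, the other not used here), in whole liver and isolated hepatocytes (horizontal), with red for higher and blue for lower and a star for genes past the threshold. The Double KO hepatocyte column holds 9 starred falls, among them Per2, Per3 and Ciart, and the IkkB KO liver column holds 4 starred rises.

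Loss of both genes in isolated hepatocytes was accompanied by lower transcripts over much of the clock list. Ciart, a clock repressor, fell from 7.32 to 1.08, Per2 from 5.78 to 1.0, Per3 from 4.89 to 0.834, Tef from 41.9 to 18.9 and Bhlhe40 from 54.2 to 26.3. Cry1, Cry2 and Hlf were also among the members that fell (10 of 19 tested members fell, 10 adjusted over the list alone); the list median was -0.46, and 0 of 10000 random lists lay as low. Dbp was 50.2 in WT and 12.5 in Double KO and did not pass, with q = 0.233 in the authors' deposited table. Arntl, Clock, Nfil3 and Nr1d1 did not pass and were 4.81, 5.17, 21.96 and 39.1 in WT and 6.44, 6.05, 26.5 and 39.2 in Double KO. Outputs Lpin1 and Upp2 fell from 88.9 to 23.7 and from 317 to 86.9 (7 of 18 tested members fell, 7 adjusted over the list alone). With no collection times in the labels, genotype and time of day were not separated in these values.

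Most tested proliferation and fetal genes rose in the same hepatocyte preparations, and lipid genes moved both ways. Non-hepatocyte markers were higher in these preparations as well, as given below, and which cells held the proliferation and fetal transcripts was not tested. Top2a rose from 0.247 to 2.39, Cdk1 from 0.458 to 2.85, Mcm6 from 1.13 to 4.48 and Ccnb2 from 0.536 to 2.92 (20 of 27 tested members rose, 21 adjusted over the list alone). Ly6d rose from 0.632 to 43.1, H19 from 0.149 to 14.1 and Scd2 from 0.565 to 5.87 (15 of 17 tested members rose, 15 adjusted over the list alone). Cyp4a14 rose from 9.77 to 342, Acot1 from 3.49 to 20.5 and Pdk4 from 0.648 to 5.32 (7 of 22 tested members rose, 7 adjusted over the list alone), and Cd36 from 2.31 to 31.7 and Pparg from 0.914 to 10.96 (6 rose and 4 fell of 21 tested members, 7 and 6 adjusted over the list alone). Cyp7a1 rose from 24.6 to 96.5 and Nr0b2 fell from 55.9 to 14.2 (2 rose and 2 fell of 16 tested members, 2 and 2 adjusted over the list alone), and of the Nrf2 list, 13 rose and 1 fell of 20 tested members (13 and 1 adjusted over the list alone), with Gstm3 from 29.6 to 194. Csad rose from 44.99 to 711. In whole liver most acute phase genes that passed were higher, though Mt1 and Mt2 were lower, with log2(value + 1) differences of -2.11 and -2.22. Here most acute phase genes that passed were lower, and the difference between the tables was not tested. Saa1 fell from 1998 to 397, Saa2 from 1299 to 266, Mt2 from 464 to 26.1 and Mt1 from 573 to 46.6 (1 rose and 7 fell of 26 tested members, 1 and 10 adjusted over the list alone). Cxcl1 fell from 32.2 to 5.93 (4 rose and 1 fell of 20 tested members, 4 and 1 adjusted over the list alone), and Spry4 from 2.78 to 0.574 (2 rose and 5 fell of 13 tested members, 5 and 5 adjusted over the list alone). Hsd3b5 fell from 149.6 to 6.02 (2 rose and 8 fell of 15 tested members, 2 and 8 adjusted over the list alone), and of the female-biased list, 5 rose and 3 fell of 13 tested members (5 and 4 adjusted over the list alone). Non-hepatocyte markers were above the WT preparations here too, Marco from 1.08 to 7.43 (13 of 16 tested members rose, 14 adjusted over the list alone), Col3a1 from 1.18 to 6.296 (14 of 17 tested members rose, 14 adjusted over the list alone) and Clec4g from 22.2 to 42.1 (10 of 16 tested members rose, 12 adjusted over the list alone). In the erythroid list, 1 of 5 tested members fell (1 adjusted over the list alone), which was Klf1, from 5.53 to 2.37. A total of 1656 of 12174 tested genes passed, 1101 higher and 555 lower.

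**Figure D3:**
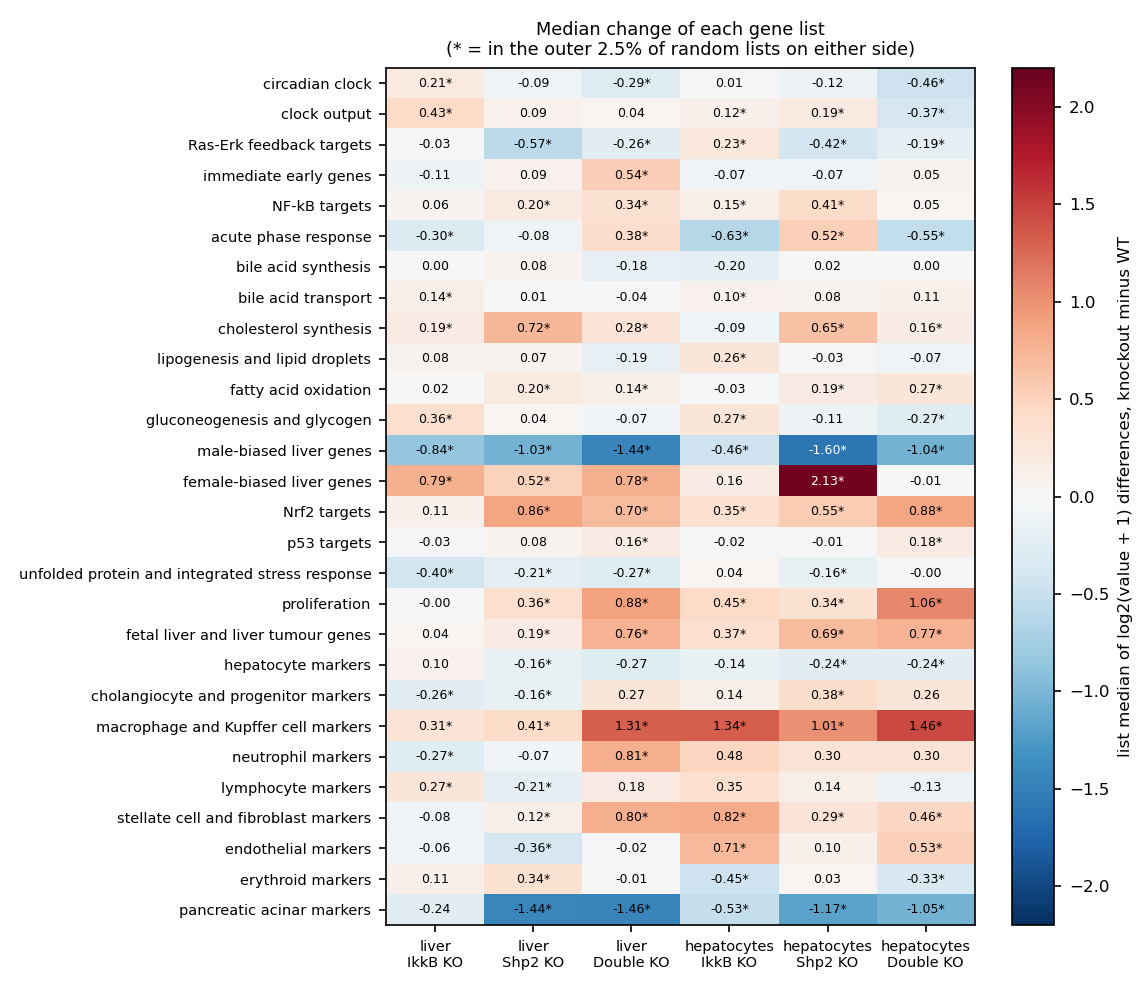
Median difference in log2(value + 1) of the tested members of each of the 28 gene lists (vertical) between each knockout and WT (horizontal), with red for higher and blue for lower. A star marks a median within the outer 2.5% of 10000 random lists on either side, as in the proliferation list of Double KO liver (0.88) and hepatocytes (1.06).

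Setting the double knockout against each single knockout asked what the second deletion added. Against IkkB KO liver, 1489 genes were higher and 970 lower of 12925 tested, and against Shp2 KO liver 1023 were higher and 365 lower of 12878. H19 was 0.549 in IkkB KO, 1.15 in Shp2 KO and 411 in Double KO, and rose against both. Marco rose against both as well, at 11.8, 5.24 and 23.4 in the same order. In liver, 604 genes rose and 168 fell in Double KO against all 3 other genotypes, with Cdk1, Col1a1, Cdkn1a and Lcn2 among those that rose and Bhlhe41, Thrsp and Hsd3b5 among those that fell. Compared with IkkB KO liver, 2 rose and 10 fell of 18 tested members (2 and 10 adjusted over the list alone) in the clock list.
Relative to Shp2 KO liver, 6 of 23 tested members fell (11 adjusted over the list alone) in the cholesterol synthesis list and 13 of 19 tested members rose (16 adjusted over the list alone) in the stellate cell list.
In hepatocytes, 709 genes were higher and 693 lower of 12321 against IkkB KO, and 422 were higher and 406 lower of 12250 against Shp2 KO. Adjustment within that last comparison alone, added after the data were seen, gave 470 genes in place of 828, and the hepatocyte q-values could not be recomputed from the table. The same adjustment lowered the other hepatocyte counts as well, by less than 1.5 times. More of the clock list passed between knockouts than against WT. Against IkkB KO, 3 rose and 13 fell of 19 tested members (3 and 13 adjusted over the list alone), with Dbp from 86.5 to 12.5 and Ciart from 10.2 to 1.08.
Against Shp2 KO, 4 rose and 11 fell of 19 tested members (4 and 12 adjusted over the list alone), with Arntl from 1.51 to 6.44, Nfil3 from 10.05 to 26.5, Per3 from 6.38 to 0.834 and Dbp from 82.2 to 12.5. The female-biased list was lower in Double KO than in Shp2 KO hepatocytes, where 13 of 16 tested members fell (14 adjusted over the list alone), and so was the acute phase list (14 of 26 tested members fell, 16 adjusted over the list alone). In the Double KO comparison with WT, 13 female-biased members were tested. A member near 0 in Double KO enters only if its Shp2 KO value is high enough, which favours falls. The Shp2 KO values are the same ones that gave the rise against WT. Against all 3 other genotypes, 148 hepatocyte genes rose, among them Mki67, Top2a and Pdk4, and 90 fell, among them Per2, Per3, Ciart, Cry2 and Tef.

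The design also allows the double knockout to be compared with the sum of the single effects, here as a value with no test. In liver, the Double KO lay at least 1 above the sum on the log2(value + 1) scale for 227 of 13060 genes and at least 1 below it for 194. In hepatocytes the numbers were 193 above and 315 below of 12525. H19 lay 7.47 from the sum in liver and -0.77 in hepatocytes. Hepatocyte Arntl lay 2.65 and Nfil3 2.65 from the sum, Dbp -3.39, Ciart -2.80 and Per3 -2.14. With a pseudocount of 0.1 in place of 1 the totals were 1035 genes in liver and 1233 in hepatocytes, and the totals depended on this setting.

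Effects were then set side by side across genes with a value of at least 1, as correlations of log2(value + 1) differences, where genes are not independent replicates. In liver, Shp2 KO and Double KO against WT had Pearson r = 0.654 and Spearman rho = 0.655 over 11186 genes, and IkkB KO and Double KO had r = 0.355 and rho = 0.231. These pairs share the WT libraries. Simulated groups without any effect, with noise sized from the authors' p-values, gave r = 0.496 and 0.494 from the shared controls alone, and covariances of 0.0149 and 0.0148, against observed covariances of 0.216 and 0.103. In hepatocytes the same pairs had r = 0.602 (rho = 0.656) and r = 0.442 (rho = 0.388), simulated r = 0.495 and 0.493, covariances of 0.263 and 0.173 and simulated covariances of 0.0198 and 0.0195. Shp2 KO and IkkB KO against WT had r = 0.403 in liver and 0.382 in hepatocytes, below the simulated r = 0.505 and 0.509. Their observed covariances were 0.0975 and 0.155 and the simulated ones 0.0154 and 0.0201. Genes higher in both Shp2 KO and Double KO numbered 474 in liver, where independent lists would share 69.5, and 521 in hepatocytes, where they would share 67.4. Part of the excess can come from the shared controls, whose libraries could not be split, and the gaps to the simulated covariances depend on a noise that no replicate values could check.

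Pairs without a shared genotype were added after the data were seen. The Shp2 effect on a WT background and on an IkkB KO background (Double KO vs IkkB KO) had r = 0.362 in liver (rho = 0.438) and 0.239 in hepatocytes (rho = 0.378). For the IkkB effect on a WT and on a Shp2 KO background, r was 0.0311 in liver (rho = -0.051) and 0.0482 in hepatocytes (rho = 0.123). Between the tables, which share no libraries, the same comparison had r = 0.485 for Double KO (rho = 0.63), 0.397 for Shp2 KO (rho = 0.579) and 0.148 for IkkB KO (rho = 0.0799) against WT. Genes higher in Double KO numbered 790 in both tables, where independent lists would share 117, and 345 were lower in both, where 37.8 would be shared. Another 14 genes passed in opposite directions, and those included Saa1, Saa2 and Lcn2.

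**Figure D4:**
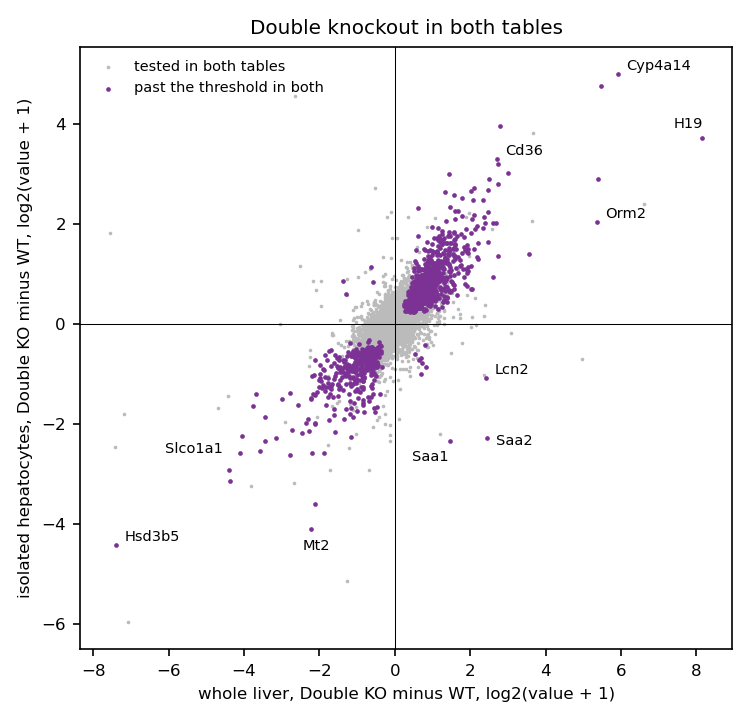
Each point is 1 of 11971 genes tested in both tables, with its Double KO minus WT difference in log2(value + 1) in whole liver (horizontal) and in isolated hepatocytes (vertical), and purple marks the 1149 genes past the threshold in both. Most purple points lie in the quadrants of equal sign, and Saa1, Saa2 and Lcn2 lie in the lower right, higher in liver and lower in hepatocytes.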

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

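The tests of explanations in the paragraphs on clock, female-biased and non-hepatocyte transcripts were chosen only after the results were seen. The gene lists with their counts past the threshold and ranks among random lists, the threshold and the rule for named genes were set before the data were examined. The genes below passed the threshold in opposite directions in a pair of like comparisons. They come from the genes chosen by the naming rule, and other genes did so too. For the Shp2 effect on the WT and IkkB KO backgrounds, 40 liver genes passed in opposite directions, beside 398 higher and 282 lower in both. In hepatocytes these numbers were 59, 310 and 237. For the IkkB effect on the WT and Shp2 KO backgrounds they were 85, 74 and 59 in liver and 82, 88 and 40 in hepatocytes. Values per library were not available, so the differences between the effects were not tested.

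In isolated hepatocytes, the effect of deleting Shp2 was set against the same deletion in IkkB KO mice. The difference between the effects, on the log2(value + 1) scale and on the WT background minus the IkkB KO background, was -2.65 for Arntl, -2.65 for Nfil3, 2.55 for Usp2, 2.76 for Cyp17a1, -2.41 for Derl3, -3.50 for Elovl3, -3.54 for Glul, -5.69 for Gm4841 and 4.34 for Marco. Glul was 109.8 in WT, 33.1 in Shp2 KO, 68.3 in IkkB KO and 246 in Double KO hepatocytes. For the deletion of IkkB without minus with deletion of Shp2, the difference was -2.80 for Cdkn1a, 3.82 for Cyp2a4, 5.93 for Cyp2b9 and 4.75 for Rgs16.

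In whole liver, the difference for the deletion of Shp2 without minus with deletion of IkkB was -4.64 for Mt1, -5.63 for Mt2 and -4.30 for Tff3. For the deletion of IkkB without minus with deletion of Shp2 it was 3.08 for Rgs16, -2.49 for S100a8, -3.33 for Saa1 and -2.94 for Saa2. Rgs16 was 38.9 in WT, 161 in IkkB KO, 2.95 in Shp2 KO and 0.885 in Double KO liver. Tff3 was 36.1, 28.2, 8.03 and 139 in the same order.

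Between the tables, the Double KO effect in whole liver minus that in hepatocytes was 3.49 for Lcn2, 3.79 for Saa1 and 4.73 for Saa2. The Shp2 KO effect differed in the same way by -4.20 for Mt1 and -4.40 for Mt2, and the IkkB KO effect by -2.94 for Ugt2b38. Whole tissue and isolated cells also differ in handling and in RNA kit, and these were not separated from the tissue.

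Clock transcripts fell in Double KO hepatocytes, where 10 of 19 list members passed. A fall of all clock transcripts alike was argued against by the 4 dawn-phase members, with a median difference of 0.226 beside -0.785 for the 10 day and dusk members. In the single knockouts the dawn members had medians of -0.727 (IkkB KO) and -0.802 (Shp2 KO), and the day and dusk members 0.277 and 0.316. A shift of the time of day at which animals or preparations were taken may give such opposite movements, and it cannot be told apart from genotype because the labels hold no times (median -0.785). Loss of both genes in hepatocytes stays open too, since 6 of the 10 members also fell in whole liver, which may share the time of collection.

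Female-biased genes rose in Shp2 KO hepatocytes, 14 of 16 tested members. A female animal in the pool was argued against by Xist at 0.00645 in Shp2 KO hepatocytes and by Y-linked genes at a median ratio of 0.886 to WT. Deletion of Shp2 as the whole cause, in any sample of these animals, cannot be told apart from a cause in the preparations. Over the 12 members tested in both tables, not chosen by direction, the median difference was 0.515 in whole liver and 1.90 in hepatocytes, and the quartiles overlapped. In whole liver 6 of these rose and 2 fell, and 0 of 10000 random lists lay as high. Over all 16 members tested in hepatocytes, not all of them tested in whole liver, the medians were 0.295 and 2.13 with pseudocount 1. Their quartiles lay apart with pseudocount 1 and overlapped with pseudocount 0.1. A rise carried by 1 of the 3 preparations may underlie the pooled value. It cannot be told apart from a rise in all 3, as 12 members were at the smallest p-value of a test that gives no value per library.

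Macrophage markers rose in most members in hepatocytes of all 3 knockouts, and stellate cell and endothelial markers did in IkkB KO and Double KO, while in Shp2 KO 5 of 15 stellate cell markers rose and no endothelial marker passed. With pseudocount 0.1 the macrophage median lay above the endothelial one by 0.6504 (IkkB KO), 1.01 (Shp2 KO) and 0.896 (Double KO). With pseudocount 1 it did so by 0.62, 0.90 and 0.93, and each gap lay beyond the quartiles of both lists. The stellate cell list overlapped with 1 of the other lists or both on each scale. The gaps argued against more carry-over of all such cells alike only for livers that did not themselves differ in these transcripts. In whole liver the 2 medians were 0.33 and -0.075 (IkkB KO), 0.50 and -0.39 (Shp2 KO) and 1.46 and -0.025 (Double KO) with pseudocount 0.1. Even carry-over from such livers may also give a gap, so it stays open. More of these transcripts in the liver itself was argued against as the whole cause in IkkB KO and Shp2 KO, but over members not matched between liver and hepatocytes. Of the macrophage list 4 of 17 and 7 of 19 tested members rose in whole liver of these genotypes, with log2(value + 1) medians of 0.31 and 0.41. In hepatocytes the medians were 1.34 and 1.01 over the 14 and 15 members tested there, and the quartiles lay apart. A member near 0 in WT hepatocytes enters only if its knockout value is high enough, which favours rises. How much of the gap this gave was not tested. In both, 0 of 10000 random lists lay as high in whole liver, so a contribution from the liver to the macrophage markers stays open. The stellate cell and endothelial lists of IkkB KO had no risen member in whole liver, and the endothelial list of Double KO had 1 of 16, which goes against the liver as the whole cause there too. For Double KO 33 members rose in whole liver, 19 of 19 of the macrophage and 14 of 19 of the stellate cell list, so a change in the liver itself may underlie these. Carry-over stays open for all 3 knockouts, in differing proportions or alike from livers that differed in these transcripts.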

How the results depend on the processing

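Alternatives were fixed before the data were examined, except Benjamini-Hochberg adjustment within each comparison alone and the pairs without a shared genotype, which were chosen only after the results were seen. No paired analysis was possible because the tables hold 1 pooled value per genotype. For the same reason the planned replicate block, leaving out each replicate in turn, fits on the compared genotypes alone, limma with and without trend, camera and other splits of the samples were not run. Depth was not given, so what it limits is unknown.

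The counts of called genes stayed within 1.5 times under a value of at least 1 in all 10 comparisons. Leaving out the filter on low values added no call and centring cannot alter the q-values, so neither tests them. With a q-value under 0.01 the count was, in liver 325 (IkkB KO vs WT) and 814 (Double KO vs Shp2 KO) and in hepatocytes 701 (IkkB KO vs WT), 896 (Shp2 KO vs WT), 1052 (Double KO vs WT), 856 (Double KO vs IkkB KO) and 462 (Double KO vs Shp2 KO), and it stayed within 1.5 times in the other 3 comparisons. With an absolute log2 difference of at least 1 added it was, in liver 98 (IkkB KO vs WT), 284 (Shp2 KO vs WT), 538 (Double KO vs WT), 525 (Double KO vs IkkB KO) and 178 (Double KO vs Shp2 KO) and in hepatocytes 238 (IkkB KO vs WT), 428 (Shp2 KO vs WT), 421 (Double KO vs WT), 368 (Double KO vs IkkB KO) and 181 (Double KO vs Shp2 KO). With pseudocount 0.1 in that difference it was, in liver 212 (IkkB KO vs WT), 539 (Shp2 KO vs WT), 1215 (Double KO vs WT), 1166 (Double KO vs IkkB KO) and 575 (Double KO vs Shp2 KO) and in hepatocytes 798 (Shp2 KO vs WT), 972 (Double KO vs WT), 701 (Double KO vs IkkB KO) and 390 (Double KO vs Shp2 KO). In hepatocytes of IkkB KO it stayed within 1.5 times. These settings lower the counts by construction, since each adds a condition. Adjustment within the comparison alone gave 470 for Double KO vs Shp2 KO in hepatocytes and stayed within 1.5 times in the other 9 comparisons; the cause was not tested. The number of genes away from the sum of the single effects was 1035 in liver and 1233 in hepatocytes with pseudocount 0.1, which widens log2 differences of low values.

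Median centring moves a list and its random lists alike, so it cannot test the 168 list medians. A median within the outer 2.5% of random lists kept that place, and any other kept its own, in 163 of 168 with pseudocount 0.1. There that place was lost by Ras-Erk feedback targets (hepatocyte, IkkB KO) 0.29, erythroid markers (liver, Shp2 KO) 0.35 and pancreatic acinar markers (hepatocyte, IkkB KO) -0.54, and gained by cholangiocyte and progenitor markers (hepatocyte, Double KO) 0.93 and lymphocyte markers (hepatocyte, IkkB KO) 1.24. With random lists not matched on expression, which leave medians as they are, 153 kept it. It was lost by bile acid transport (hepatocyte, IkkB KO) 0.10, fatty acid oxidation (liver, Double KO) 0.14 and cholangiocyte and progenitor markers (liver, Shp2 KO) -0.16, and gained by bile acid synthesis (hepatocyte, IkkB KO) -0.20, lipogenesis and lipid droplets (liver, IkkB KO) 0.0817, lipogenesis and lipid droplets (liver, Double KO) -0.19, female-biased liver genes (hepatocyte, IkkB KO) 0.16, Nrf2 targets (liver, IkkB KO) 0.11, hepatocyte markers (liver, IkkB KO) 0.0951, hepatocyte markers (liver, Double KO) -0.27, hepatocyte markers (hepatocyte, IkkB KO) -0.14, cholangiocyte and progenitor markers (liver, Double KO) 0.27, cholangiocyte and progenitor markers (hepatocyte, Double KO) 0.26, neutrophil markers (hepatocyte, IkkB KO) 0.48 and lymphocyte markers (hepatocyte, IkkB KO) 0.35. With members at a value of at least 1, which left 3 combinations without a member, 155 kept it, and 3 changed sign: female-biased liver genes (hepatocyte, Double KO) 0.45, cholangiocyte and progenitor markers (hepatocyte, Shp2 KO) -0.44 and cholangiocyte and progenitor markers (hepatocyte, Double KO) -0.28. The place was lost by Ras-Erk feedback targets (hepatocyte, IkkB KO) 0.15, bile acid transport (hepatocyte, IkkB KO) 0.0397, hepatocyte markers (hepatocyte, Double KO) -0.24, lymphocyte markers (liver, Shp2 KO) -0.17 and erythroid markers (hepatocyte, Double KO) -0.34, and gained by immediate early genes (liver, IkkB KO) -0.21 and female-biased liver genes (hepatocyte, IkkB KO) 0.29. Fewer members remain there, and the cause was not tested.

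Pearson r across genes moved by at most 0.1 with all genes and with pseudocount 0.1. Among genes past the threshold in either comparison it moved further in 10 of 15 pairs, to 0.783 (liver Shp2 KO vs WT and liver Double KO vs WT, from 0.654), 0.623 (liver Shp2 KO vs WT and liver Double KO vs IkkB KO, from 0.362), 0.740 (hepatocyte Shp2 KO vs WT and hepatocyte Double KO vs WT, from 0.602), 0.272 (hepatocyte Shp2 KO vs WT and hepatocyte IkkB KO vs WT, from 0.382), 0.552 (hepatocyte Shp2 KO vs WT and hepatocyte Double KO vs IkkB KO, from 0.239), 0.154 (hepatocyte IkkB KO vs WT and hepatocyte Double KO vs Shp2 KO, from 0.0482), 0.473 (liver IkkB KO vs WT and hepatocyte IkkB KO vs WT, from 0.148), 0.750 (liver Shp2 KO vs WT and hepatocyte Shp2 KO vs WT, from 0.397), 0.811 (liver Double KO vs WT and hepatocyte Double KO vs WT, from 0.485) and 0.7003 (liver Double KO vs IkkB KO and hepatocyte Double KO vs IkkB KO, from 0.376); the cause was not tested. For the 8 target values and the 625 single named values, a pseudocount cannot turn a direction and centring removed medians of at most 0.0311, so neither tests them.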

Other observations

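No further tests were made for the values below, all of which were picked out after the results were seen. Csad, which makes taurine precursors, was 74.4 in WT, 86.4 in IkkB KO, 749 in Shp2 KO and 520.5 in Double KO liver. In hepatocytes Csad was 44.99, 38.8, 544 and 711 in the same order. Cela1 was 34.6, 26.98, 6.24 and 5.92 in liver and 26.7, 11.9, 5.596 and 6.04 in hepatocytes. Igtp was 20.5 in WT and 92.2 in IkkB KO liver, against 23.4 in Shp2 KO and 26.8 in Double KO. Alb was listed at 0 in every genotype of both tables, and Apoa1 at 0 in WT and IkkB KO liver and in IkkB KO hepatocytes, because these transcripts were too abundant for Cuffdiff to estimate.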
